A study of Homo sapiens with 8 samples.

How the data were processed

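RNA of cardiomyocytes derived from the H9 human embryonic stem cell line was measured on 8 Affymetrix HG-U133 Plus 2.0 arrays, 2 for each of 0, 0.1, 1 and 10 µM doxorubicin given for 24 h, per the labels. The labels' protocols name chemically defined medium up to day 30, total RNA extracted on columns, and biotin labelling. The deposited value table holds log2 signals of 54675 probe sets, 1 column per array. That the values are log2 was read from the values themselves, since differences of group means matched log2 of the fold changes in the authors' lists. Background correction, summarisation and normalization between arrays are not given in the sources used here. Per the file headers, the authors also deposited 6 lists of changed probe sets, with a linear fold change (a ratio) and a p-value for each, chosen at a corrected p-value of 0.05 or less and a fold change of 2 or more. The test behind that p-value is not given in the sources used here. Any normalization that makes arrays equal on average expresses each transcript relative to the rest of its array, so a change shared by most transcripts would not appear on the deposited scale.

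The 62 control probe sets were set aside and the other 54613 were analysed as deposited, with no further normalization and no filter on dim probe sets. Names came from the authors' lists alone, since they are the files that pair probe sets with symbols here. Of 11127 listed probe sets, 7 were control probe sets, 10117 had 1 symbol, 158 several and 845 none. Symbols were updated through Entrez identifiers with a RefSeq gene table (assembly GRCh38.p14, used for names only), which matched 9986 of the 10117, and 131 kept the symbol of the list. A total of 44496 tested probe sets (named ones being 18.5%) stayed unnamed here. The 10117 probe sets represent 7163 genes, each of which took the listed probe set with the highest mean over the 8 arrays. The design written beforehand had 1 value per gene, but counts are given over all probe sets because names exist for selected probe sets only, and the count over named genes became an alternative. Of the 2150 genes with several listed probe sets, 0 were called in both directions at 0.1 µM against 0 µM, 34 at 1 µM, 81 at 10 µM, 35 for 1 against 0.1 µM and 87 for 10 against 1 µM. No coordinates are given because no genome build was named.

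limma 3.58.1 in R 4.3.3 was used for 1 linear model over all 8 arrays with a mean per dose (4 residual degrees of freedom, 4.94 added by the prior), two-sided moderated tests, and Benjamini-Hochberg adjustment over all probe sets within each of 5 comparisons. A call is an adjusted p under 0.05. Array number limits the precision. Nothing in the labels says whether the 2 arrays of a dose came from separate cultures, so p-values measure only the spread between these samples, which may be technical. A total of 32 gene lists with 1080 entries was fixed before the data were examined and tested with camera (preset correlation 0.01) over the named genes, adjusted over the lists and comparisons together. camera with an estimated correlation and fry were run beside it. The former rests on the 4 residual degrees of freedom and has little power here, so a lost call does not show that a list did not move. The preset correlation, in turn, treats the genes of a list as nearly independent. Where they vary together on these few arrays, the p-values of camera with it may be far too small. fry tests whether a list moves, on balance, one way, without comparing it with other genes. The p53 and death receptor lists share members, as do several others. The genes named in the text followed a rule also fixed beforehand. For each dose against 0 µM these are the 10 greatest increases and decreases past the threshold with both arrays on the same side, 5 each way for neighbouring doses, up to 4 called and 2 not passing members per called list, 5 of each kind that turned back, and a fixed set of always-named genes. Unnamed loci and small RNA symbols were left out of the top genes, and some genes that the rule names are not reported here. Plots were drawn with matplotlib 3.10.9 in Python 3.11.15.

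The scripts were tested on simulated arrays with the measured means and spread. For 1 µM against 0 µM, with 54613 probe sets, 43 of 100 planted 2-fold changes and 100 of 100 planted 4-fold changes were recovered, with 12 false calls. Over 7163 named genes, the planted list was called, and 0 of the other lists. The simulated noise was independent between genes and alike at all doses, the lists were random, and few probe sets were changed. This simulation therefore cannot tell how often camera falsely calls lists whose members vary together. Nor does its recovery carry over directly to the measured arrays. Expected overlaps without an effect came from 20 simulations of unchanged groups against the shared arrays, as calls and, chosen after the data were seen, as lists of the observed sizes with the lowest p-values in each direction. Alternatives chosen before the data were examined were quantile normalization, centring each array on its median, leaving out the lowest 30% of probe sets by mean signal, other ways of choosing a gene's probe set, a robust prior with a trend, a fit on the 4 compared arrays alone, the replicate number as a block, a fold limit of 2, an adjusted p under 0.01, and leaving out each array. When an array is left out, the lone array of its dose is assumed to vary like the other groups. Centring on the poly-A or the hybridization control probe sets, with the replicate number as a block, and 1 value per named gene were chosen after the data were seen.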

Results

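The arrays measured RNA from cardiomyocytes derived from H9, an established human embryonic stem cell line, at day 30 of differentiation. The cells had been exposed for 24 h to doxorubicin, an anthracycline used in chemotherapy that poisons type II topoisomerases and can injure the heart. Each of the doses 0.1, 1 and 10 µM, and the untreated control (0 µM), was represented by 2 arrays, which gave 8 Affymetrix HG-U133 Plus 2.0 arrays in total. The comparisons address how transcript levels in these cells changed with the dose. After the control probe sets were set aside, 54613 probe sets were tested, and 7163 genes could be named. Names came from the authors' deposited lists of changed probe sets, so every named gene had been selected by the authors as changed at 1 or more doses. Counts within the gene lists described here are therefore not independent evidence of direction, and the list test set each list against the other named genes. A list that it did not call may still have moved along with those genes. Its p-values treat the members of a list as nearly independent and may be far too small. A gene with several listed probe sets is given by the one with the highest mean. With the mean of them instead, 32 of 330 named values moved by more than 1.5-fold, and with the one of largest spread 11 did. Members of a list without a name in these data may or may not have changed. They had no probe set with 1 symbol in the authors' lists, so the called share of named members can exceed that of a full list. For example, names covered 3 of 18 endoderm and liver markers, 10 of 60 ribosomal protein, 29 of 67 histone and 22 of 58 oxidative phosphorylation genes. Where a list's count adjusted over the list alone is not given, it equalled the count adjusted over all probe sets. RARG, TNNT2, MYH7, NPPA, NPPB and ATP2A2 had no named probe set.

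Mean log2 signal was close to equal on the 8 arrays, between 5.06 and 5.09. The interquartile range lay between 3.10 and 3.28 on the arrays of 0, 0.1 and 1 µM, and was 2.64 and 2.61 on the arrays of 10 µM. Across probe sets, which are not independent replicates, the arrays of a dose correlated with r = 0.991 at 0 µM, 0.991 at 0.1 µM, 0.984 at 1 µM and 0.984 at 10 µM. The first principal component held 57.5% of the variance and separated 1 µM from 10 µM, with the arrays of 0 and 0.1 µM between them. The next component held 29.2% and separated the arrays of 0 and 0.1 µM from those of 1 and 10 µM. With 2 arrays per dose, the number of arrays limits the precision of every value.

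Control probe sets, which match bacterial or phage RNA added during processing, also moved with dose. The 12 poly-A control probe sets differed from 0 µM by -0.20 on the log2 scale at 0.1 µM, 0.96 at 1 µM and 2.61 at 10 µM. The 9 hybridization control probe sets differed by 0.01, 0.18 and 0.59. Both kinds were also brighter in replicate number 2 than in replicate number 1 at every dose, by 1.56 to 2.38 for the poly-A controls and by 0.51 to 1.11 for the hybridization controls. Centring each array on the poly-A controls, with the replicate number as a block, gave a median log2 fold change over all probe sets of 0.212 at 0.1 µM, -0.991 at 1 µM and -2.43 at 10 µM against 0 µM. It gave -1.21 for 1 against 0.1 µM and -1.43 for 10 against 1 µM. Centring on the hybridization controls gave medians of -0.214 at 1 µM, -0.402 at 10 µM, -0.223 for 1 against 0.1 µM and -0.181 for 10 against 1 µM. On the deposited scale the medians were 0.013 at 0.1 µM, -0.032 at 1 µM, 0.19 at 10 µM, -0.054 for 1 against 0.1 µM and 0.22 for 10 against 1 µM. The changes given here are on the deposited scale, that is, relative to the bulk of the transcripts on each array. Where the sign of a called value, or of the median of a called list, turns under a control centring, that is said beside it. Values that did not pass turn under these centrings as well. Each centring shifts all probe sets of an array alike, including those near the floor, whose signal can hardly fall further. The trpn control probe sets, which have no human target, stood 0.30 higher at 10 µM as deposited, yet poly-A control centring would place them lower. Lower counts and turned signs of dim probe sets under that centring are therefore no evidence of a fall.

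**Figure D1:**
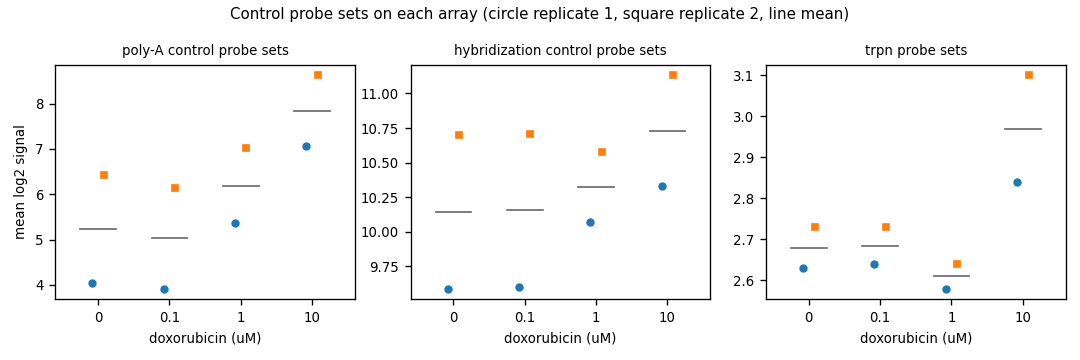
Mean log2 signal of the poly-A, hybridization and trpn control probe sets on each array (vertical axes, each with its own range that does not start at 0) against doxorubicin dose in µM (horizontal axes, doses evenly spaced); circles are replicate 1, squares replicate 2 and lines the mean of both. The poly-A controls were 2.61 higher at 10 µM than at 0 µM, the hybridization controls 0.59 higher and the trpn probe sets 0.30 higher.

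At 0.1 µM, 14 of 36 named target genes of the transcription factor p53 were higher and 36 of 47 genes of mitosis and DNA replication lower, while 22 and 11 did not pass. The p53 list call held with an estimated correlation (adjusted p = 0.035) and the mitosis call was lost (adjusted p = 0.31). The highest increase among the named genes was that of GDF15, a stress-induced cytokine, from a log2 signal of 5.19 ± 0.32 to 9.55 ± 0.09 (SD, n = 2 each), a log2 fold change of 4.37 ± 0.45 (SE; adjusted p = 0.0079). CDKN1A, which encodes the cell cycle inhibitor p21, rose by 1.92 ± 0.16 (SE; adjusted p = 0.0042), and MDM2, the ubiquitin ligase that targets p53, by 1.52 ± 0.16 (adjusted p = 0.0076). The greatest decrease was that of KIF20A, a kinesin of cytokinesis, from 8.32 to 3.38, a log2 fold change of -4.94 ± 0.19 (adjusted p = 6.8e-05). TOP2A, the topoisomerase II isoform of dividing cells, had a log2 fold change of -2.86 ± 0.27 (adjusted p = 0.0054), whereas that of TOP2B, the isoform of non-dividing cells, was -0.32 ± 0.27 and did not pass (adjusted p = 1).

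Of the 36 named p53 targets, 14 were higher, 0 lower and 22 did not pass at 0.1 µM, and adjusted over the list alone 31 were higher and 0 lower. Their median log2 fold change was 1.18 and the list test gave an adjusted p of 1.1e-40. This was the single list call of the 44 that held with an estimated correlation (adjusted p = 0.035). Besides GDF15 and CDKN1A, it held FDXR, a mitochondrial ferredoxin reductase (2.57), and SPATA18, a factor in mitochondrial quality control (2.06), whereas CCNG1 stood at 0.10 and did not pass. Of 24 death receptor and apoptosis genes, 4 were higher, 0 lower and 20 did not pass, and adjusted over the list alone 7 were higher. The list gave an adjusted p of 6.1e-06, which became adjusted p = 0.31 with an estimated correlation. The 4 higher genes were TNFRSF10A (2.06) and TNFRSF21 (1.33), both death receptors, TNFRSF10D (1.09), a decoy receptor, and BAX (1.31), a pore-forming apoptosis effector. TNFRSF10A stood at 1.39 for the mean of its listed probe sets, and its call was lost under quantile normalization. FAS, another death receptor, stood at 1.46 ± 0.24 and did not pass (adjusted p = 0.051). With the replicate block, TNFRSF10D stood at 1.29 under poly-A control centring (adjusted p = 0.092) and at 1.08 under hybridization control centring (adjusted p = 0.055), so that it no longer passed although its fold change was about as large.

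Of 47 genes of mitosis and DNA replication, 36 were lower, 0 higher and 11 did not pass at 0.1 µM, and adjusted over the list alone 43 were lower and 1 higher. The median was -2.14 and the adjusted p was 7e-63, with adjusted p = 0.31 with an estimated correlation. DLGAP5, a spindle protein (-3.69), ASPM, a spindle pole protein (-3.55), and CENPA, the centromeric histone H3 (-3.38), were among the lowest. For the mean of its listed probe sets, ASPM stood at -2.22. TYMS (0.11) and PCNA (0.39), both of DNA synthesis, did not pass. Of 23 DNA damage signalling and repair genes, 3 were lower, 0 higher and 20 did not pass, and adjusted over the list alone 10 were lower and 1 higher (adjusted p = 0.00083; adjusted p = 0.31 with an estimated correlation). The 3 were H2AX (-1.26), a histone phosphorylated at DNA breaks, FANCD2 (-1.21) and FANCI (-1.10), the Fanconi anaemia pair. They stood at -1.06, -1.01 and -0.90 under poly-A control centring, and none passed. The call of FANCI was also lost with the replicate number as a block and no centring.

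Smaller list shifts at 0.1 µM rested on few called members. Of 29 replication-dependent histone genes 1 was higher, 0 lower and 28 did not pass, with 12 higher and 1 lower adjusted over the list alone (median 0.49, adjusted p = 9.4e-09; adjusted p = 0.39 with an estimated correlation). The called gene was H2BC8 at 1.86. Of 40 immediate early and short-lived transcripts, 2 were higher, IER5 (1.24) and DUSP6 (1.23), 0 lower and 38 did not pass, with 3 higher adjusted over the list alone (adjusted p = 3e-04; adjusted p = 0.52 with an estimated correlation). Of 17 interferon-stimulated genes, 1 was higher, the antiviral TRIM22 (2.56), 0 lower and 16 did not pass, with 4 higher and 1 lower adjusted over the list alone (adjusted p = 0.0054; adjusted p = 0.52 with an estimated correlation). The remaining named genes with the greatest increases were GAS6-AS1, an antisense transcript listed as FLJ41484 (3.87), PCDH8, a protocadherin (2.72), MUC19, a mucin (2.24), and DDB2, a DNA damage recognition protein (1.87). Among those that fell were CDC20, the activator of the anaphase-promoting complex (-3.33), NEK2, a centrosomal kinase (-3.30), CENPE, a kinetochore kinesin (-3.25), FAM83D (-3.15), NDC80, a kinetochore protein (-3.09), and HMMR (-3.03). Sarcomere genes did not pass as a list (0 of 22 members called, median -0.12, or 0.08 under poly-A control centring, adjusted p = 0.46), and MYH6, the atrial myosin heavy chain, stood at 0.08 ± 0.17 (adjusted p = 1). RYR2 (-0.38), PPARGC1A (0.35), NKX2-5 (0.16), TOP1 (-0.06) and TNFRSF10B (1.18, adjusted p = 0.095) did not pass either.

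Over all probe sets, 59 were higher and 137 lower at 0.1 µM than at 0 µM with limma (57 and 136 of at least 2-fold), and 2477 had an unadjusted p under 0.05. The higher share was 30.1%, against 49.8% under poly-A control centring, where 101 were higher, and under hybridization control centring 119 were higher and 246 lower. Of the 32 lists, 5 were called upward and 2 downward. These counts depended on single arrays, with 10 higher and 61 lower without 0 µM replicate 1, 3 and 3 without 0 µM replicate 2, 2 and 2 without 0.1 µM replicate 1, 10 and 72 without 0.1 µM replicate 2, and 35 and 85 with each array of 10 µM left out in turn. Of the 31 called genes named at this dose, 4 still passed without 0.1 µM replicate 1 (GAS6-AS1, PCDH8, KIF20A and CDC20), 6 without 0 µM replicate 2, and 18 without 0 µM replicate 1 or without 0.1 µM replicate 2, and none changed sign.

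**Figure D2:**
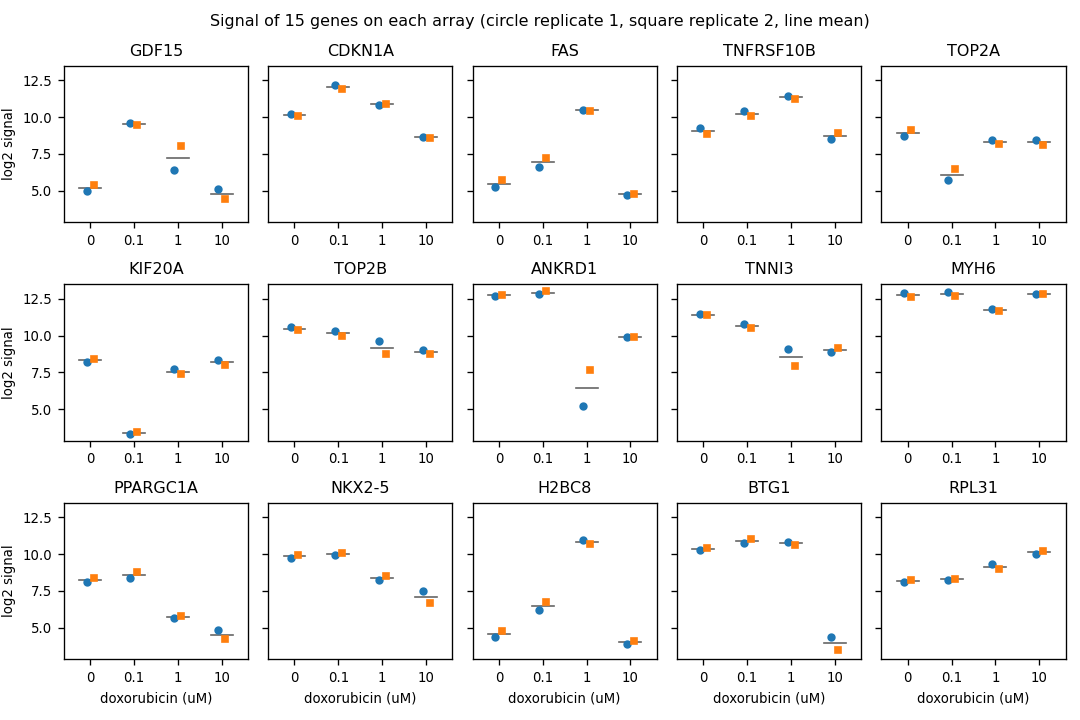
Log2 signal (vertical axes, a common range that does not start at 0) of 15 genes on each array against doxorubicin dose in µM (horizontal axes, doses evenly spaced); circles are replicate 1, squares replicate 2 and lines the mean of both. KIF20A lay at 8.32 at 0 µM and 3.38 at 0.1 µM, FAS rose to 10.48 at 1 µM, ANKRD1 lay at 12.73 at 0 µM and 6.45 at 1 µM, and BTG1 lay at 10.34 at 0 µM and 3.94 at 10 µM.

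At 1 µM, 28 of 29 named histone genes and 28 of 36 p53 targets were higher and 21 of 22 sarcomere genes lower. All 3 list calls were lost with an estimated correlation (adjusted p = 0.38, 0.31 and 0.31). FAS rose from 5.47 to 10.48, a log2 fold change of 5.0 ± 0.24 (SE, n = 2 per dose; adjusted p = 4e-06), and TNFRSF10A by 5.65 ± 0.32 (adjusted p = 8.1e-06). ANKRD1, a stretch-responsive cardiac repressor protein, went from 12.73 to 6.45, a log2 fold change of -6.28 ± 0.59 (adjusted p = 9.1e-05). Its arrays at 1 µM lay at 5.25 and 7.66, and the change was -5.07 without 1 µM replicate 1 and -7.49 without 1 µM replicate 2. TNNI3, which encodes cardiac troponin I, changed by -2.91 ± 0.31 (adjusted p = 2e-04), and MYH6 by -1.0 ± 0.17 (adjusted p = 0.0029). TOP2B changed by -1.29 ± 0.27 (adjusted p = 0.0081), although not past the threshold without 0 µM replicate 1, and TOP2A stood at -0.63 ± 0.27 (adjusted p = 0.15) and TOP1, the type I topoisomerase, at 0.29 ± 0.18 (adjusted p = 0.36). The difference between 3-prime and 5-prime control probe sets, a sign of RNA quality, moved with this dose for actin, from 1.82 ± 0.11 at 0 µM to 2.26 ± 0.07 at 1 µM on the log2 scale (SD, n = 2 each), but not for GAPDH, with 0.54 ± 0.12 and 0.43 ± 0.13. At 0.1 and 10 µM it was 1.54 ± 0.15 and 1.80 ± 0.32 for actin.

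Of the 36 p53 targets, 28 were higher, 1 lower and 7 did not pass at 1 µM, and adjusted over the list alone 30 were higher and 1 lower. Their median was 1.67 (adjusted p = 8.7e-06; adjusted p = 0.31 with an estimated correlation), and 0.71 under poly-A control centring, with 18 higher and 3 lower. PMAIP1, the apoptosis inducer NOXA, rose by 4.30, FDXR by 3.90 and DDB2 by 3.02, while TRIAP1 (0.23) did not pass. MDM2 was 1.37 ± 0.16 higher, but at 0.41 and not past the threshold under poly-A control centring, and another of its listed probe sets, that with the largest spread, stood at 0.09 and did not pass. GDF15 was 2.02 ± 0.45 higher, a call lost without 0 µM replicate 1, and stood at 2.83 without 1 µM replicate 1 and 1.20 without 1 µM replicate 2. CDKN1A was 0.71 ± 0.16 higher, with -0.25 under poly-A control centring, and its call was lost without 0 µM replicate 2, without 1 µM replicate 2 and under hybridization control centring (0.53). Of 24 death receptor and apoptosis genes, 17 were higher, 1 lower and 6 did not pass, with 17 and 2 adjusted over the list alone (median 1.02, adjusted p = 0.0072; adjusted p = 0.5 with an estimated correlation). Under poly-A control centring that median was 0.06, with 7 higher and 5 lower, and under hybridization control centring 12 were higher and 1 lower. TNFRSF10D rose by 4.48 and TNFRSF10B by 2.31, whereas MCL1, an anti-apoptotic protein, stood at -0.30 and did not pass.

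Of 29 replication-dependent histone genes, 28 were higher, 0 lower and 1 did not pass at 1 µM, and the median was 3.12 (adjusted p = 3.5e-09; adjusted p = 0.38 with an estimated correlation). H2BC8 rose by 6.21, H3C10 by 5.85, H2AC11 by 5.76 and H2AC8 by 5.75, while H4C3 stood at -0.17. Of 17 interferon-stimulated genes, 13 were higher, 3 lower and 1 did not pass (median 2.10, or 1.14 under poly-A control centring; adjusted p = 0.0091; adjusted p = 0.52 with an estimated correlation). TAP1, an antigen peptide transporter, rose by 3.65 and HERC5, a ligase of the ubiquitin-like protein ISG15, by 3.55, but IFIT1, an interferon-induced RNA-binding protein, changed by -3.03. Of 24 ribosome biogenesis genes, 17 were higher, 0 lower and 7 did not pass, with 18 and 2 adjusted over the list alone (median 0.99, adjusted p = 0.0063; adjusted p = 0.31 with an estimated correlation). Under poly-A control centring their median was 0.03 and the list was no longer called (adjusted p = 0.054). UTP15 rose by 2.11, POLR1C by 2.05, NOP56 by 1.92 and UBTF, a polymerase I transcription factor, by 1.91.

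Of 22 sarcomere genes, 21 were lower, 0 higher and 1 did not pass at 1 µM, and the median was -1.99 (adjusted p = 1.5e-07; adjusted p = 0.31 with an estimated correlation). LMOD2, a thin-filament length regulator, changed by -5.24, SYNPO2L by -4.02 and XIRP2 by -3.33, while MYOM2 stood at -0.33. Of 22 calcium handling and ion channel genes, 15 were lower, 2 higher and 5 did not pass, with 16 and 3 adjusted over the list alone (median -1.08, adjusted p = 0.0046; adjusted p = 0.52 with an estimated correlation). JPH2, which anchors the sarcoplasmic reticulum to T-tubules, changed by -3.80, SLC8A1, the sodium-calcium exchanger, by -3.44 (-6.69 for its probe set with the largest spread), and CACNA1C, the L-type calcium channel, by -2.61. RYR2, the calcium release channel, changed by -1.10 ± 0.18. Of 12 genes of the natriuretic peptide and load-stress list, 10 were lower, 1 higher and 1 did not pass (median -2.09, adjusted p = 0.0028; adjusted p = 0.31 with an estimated correlation), with FHL2 at -3.14, ACTA1 at -3.09 and EDN1, the vasoconstrictor endothelin, at -2.80. Without 1 µM replicate 1 and without 1 µM replicate 2, SYNPO2L stood at -3.31 and -4.72 and ACTA1 at -2.12 and -4.05.

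Of 22 oxidative phosphorylation genes, 14 were lower, 2 higher and 6 did not pass at 1 µM, with 14 and 3 adjusted over the list alone. Their median was -1.25 (adjusted p = 0.0035; adjusted p = 0.52 with an estimated correlation). NDUFV2 of complex I changed by -2.45, COX7B of complex IV by -2.39, and the ATP synthase subunits ATP5MC3 and ATP5F1C by -2.26 and -2.07, while NDUFB9 (-0.26) and NDUFV1 (0.48) did not pass. PPARGC1A, a coactivator of mitochondrial biogenesis, changed by -2.50 ± 0.24. Of 15 cholesterol synthesis genes, 10 were lower, 0 higher and 5 did not pass (median -1.32, adjusted p = 0.0081; adjusted p = 0.74 with an estimated correlation), among them SQLE, squalene epoxidase (-2.46), STARD4, a sterol transfer protein (-2.09), and FDPS, farnesyl diphosphate synthase (-1.79), while IDI1 stood at -0.35 and did not pass. Of 6 smooth muscle markers, 6 were lower (median -1.57, adjusted p = 0.023; adjusted p = 0.47 with an estimated correlation), among them LMOD1 (-3.73) and MYLK (-1.64), the latter not past the threshold without 0 µM replicate 2. LMOD1 stood at -2.93 and MYLK at -0.98 without 1 µM replicate 1, and at -4.53 and -2.30 without 1 µM replicate 2.

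Among the other greatest named increases at 1 µM, NHLH2, a neuronal transcription factor, rose by 6.60, SLC4A11, a borate transporter family member, by 6.45 (4.04 for the mean of its listed probe sets), and CNR1, the cannabinoid receptor, by 6.24. ZCCHC12 rose by 6.08, CA2, a carbonic anhydrase, by 6.01, and NPTX2, a neuronal pentraxin, by 5.81. The remaining named decreases were those of VCAM1, an adhesion molecule (-5.52), ASB2, a muscle ubiquitin ligase component (-5.44), STYXL2 (-4.88), ITGB1BP2 (-4.59), TGFB1I1 (-4.58), KLHL31 (-4.55, with -3.87 and -5.22 without 1 µM replicate 1 and 2 in turn), NPY6R (-4.31) and TNS1 (-4.29). NKX2-5, a cardiac transcription factor, changed by -1.44 ± 0.25. The list of cardiac transcription factors was not called, with 5 of 18 higher and 8 lower, and 6 and 9 adjusted over the list alone (adjusted p = 0.39). Nor were the neural and ectoderm markers, with 1 of 4 higher and 2 lower (median -0.91, adjusted p = 0.45). The mitosis list, lower at 0.1 µM, was not called at 1 µM against 0 µM either, with 11 of 47 higher and 20 lower, and 13 and 22 adjusted over the list alone (adjusted p = 0.28).

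Over all probe sets, 6309 were higher and 5927 lower at 1 µM than at 0 µM (4172 and 3630 of at least 2-fold). The higher share was 51.6%, against 39.6% under hybridization control centring and 4.17% under poly-A control centring, where 1766 were higher and 40577 lower. Without 0 µM replicate 2, 3947 were lower. Of the 32 lists, 5 were called upward and 6 downward, and 20 were not called. The medians of the 6 called downward lay between -3.05 and -2.04 under poly-A control centring.

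At 10 µM, 36 of 40 named immediate early and short-lived transcripts and 16 of 18 cardiac transcription factors were lower, while 4 and 2 did not pass. Both list calls were lost with an estimated correlation (adjusted p = 0.5 for each). PPP1R3C, a glycogen-targeting phosphatase subunit, went from 11.00 to 3.91, a log2 fold change of -7.09 ± 0.30 (SE, n = 2 per dose; adjusted p = 1.8e-06), or -4.12 for the mean of its listed probe sets. BTG1, an anti-proliferative factor with an unstable transcript, changed by -6.40 ± 0.27 (adjusted p = 1.8e-06), and GATA4, a cardiac transcription factor, by -3.58 ± 0.28 (adjusted p = 2.5e-05). MYH6, in contrast, stood at 0.11 ± 0.17 on the deposited scale (adjusted p = 0.65), at -0.48 under hybridization control centring and at -2.50 under poly-A control centring. CDKN1A, higher at 0.1 µM, was below its untreated level at 10 µM, by -1.54 ± 0.16 (adjusted p = 0.00014).

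Among all 7163 named genes, against which the lists were tested, 1391 were higher and 4039 lower at 10 µM (median -1.02). Of 40 immediate early and short-lived transcripts, 36 were lower, 0 higher and 4 did not pass at 10 µM, and adjusted over the list alone 37 were lower. The median was -3.35 (adjusted p = 3.7e-06; adjusted p = 0.5 with an estimated correlation). IER3 changed by -5.60, CITED2 by -5.47 and JUND by -5.28, while EGR2 (-0.96, with -1.58 and -0.34 without 0 µM replicate 1 and 2 in turn) and DUSP2 (-0.10) did not pass. Of 18 cardiac transcription factors, 16 were lower, 0 higher and 2 did not pass (median -1.82, adjusted p = 0.03; adjusted p = 0.5 with an estimated correlation). HEY2 changed by -4.67, GATA6 by -4.42, ZFPM2 by -4.03 and NKX2-5 by -2.77, while TBX2 stood at -0.28 and NR2F1 at 0.11, or -0.48 under hybridization and -2.51 under poly-A control centring. Of 30 zinc finger (ZNF) genes, 24 were lower, 1 higher and 5 did not pass, with 25 and 1 adjusted over the list alone (median -1.40, adjusted p = 0.03; adjusted p = 0.5 with an estimated correlation; adjusted p = 0.12 under poly-A control centring). ZNF12 changed by -4.75, ZNF146 by -3.71 and ZNF24 by -2.69, and ZNF37A stood at -0.45. For the mean of their listed probe sets, ZNF12 stood at -2.98 and ZNF146 at -2.99. The medians of these 3 lists were -5.96, -4.44 and -4.02 under poly-A control centring. The natriuretic peptide and load-stress list had 10 of 12 lower and 0 higher, with a median of -2.06, but was not called against the other named genes (adjusted p = 0.15).

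The medians of the 4 lists called upward at 10 µM turned negative when arrays were centred on the poly-A controls. The list test, which sets a list against the other named genes, reversed no list under that centring. The centring shifts all genes of an array alike, so the shift largely cancels in this test. Calls that were not reversed are therefore no separate support. The ribosomal protein and histone lists stayed called upward. Of 10 ribosomal protein genes, 9 were higher, 1 lower and 0 did not pass, with a median of 1.20, or 0.61 under hybridization and -1.42 under poly-A control centring (adjusted p = 9.2e-05; adjusted p = 0.31 with an estimated correlation). RPS23 stood 2.00 higher, RPL31 1.94 and RPL23 1.89, and these became -0.61, -0.67 and -0.73 under that centring. The named genes, all selected as changed, had a median of -1.02 at 10 µM, while all probe sets had 0.19. Against the named genes, a list can therefore be called upward with a median near that of all probe sets. Of 29 histone genes, 9 were higher, 1 lower and 19 did not pass, with 10 and 1 adjusted over the list alone and a median of 0.41 (adjusted p = 0.00014; adjusted p = 0.52 with an estimated correlation; adjusted p = 0.1 with fry). That median was -0.17 under hybridization control centring and -2.20 under poly-A control centring. H2BC4 (1.57) and H1-2 (1.39) were higher and H4C3 lower (-3.47), with -1.04 and -1.22 for H2BC4 and H1-2 under poly-A control centring.

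The other 2 lists called upward at 10 µM were markers of other cell types. Of 6 smooth muscle markers, 3 were higher, 0 lower and 3 did not pass at 10 µM, with a median of 0.76, or 0.17 under hybridization and -1.85 under poly-A control centring (adjusted p = 0.043; adjusted p = 0.5 with an estimated correlation). This call was lost without 0 µM replicate 2 (adjusted p = 0.053), without 1 µM replicate 1 (0.052), without 1 µM replicate 2 (0.051), without 10 µM replicate 2 (0.057) and under poly-A control centring (0.067). The 3 were TAGLN (1.57), MYLK (1.09) and CALD1 (0.90), and CALD1 had other listed probe sets called in the opposite direction. The mean of its listed probe sets stood at 0.42 and did not pass, while the one with the largest spread stood at 1.83 and passed. The 3 stood at -1.04, -1.52 and -1.71 under poly-A control centring, and the calls of MYLK and CALD1 were lost without 0 µM replicate 2 and without 10 µM replicate 2, that of MYLK also without 0 µM replicate 1, without 10 µM replicate 1 and with any 1 array of 0.1 µM left out. Under hybridization control centring MYLK stood at 0.51 and CALD1 at 0.32, and neither passed. Of 18 endoderm and liver markers on the list, 3 had a name. All 3 were higher, with a median of 1.21, or -1.41 under poly-A control centring (adjusted p = 0.019; adjusted p = 0.52 with an estimated correlation; adjusted p = 0.055 under poly-A control centring). EPCAM, an epithelial adhesion molecule, stood 1.28 higher, AFP, alpha-fetoprotein, 1.21 and APOA1, an apolipoprotein, 1.13. Under hybridization control centring they stood at 0.70, 0.62 and 0.54 and none passed, and under poly-A control centring they stood at -1.33, -1.41 and -1.49. The remaining marker lists were not called at 10 µM. Fibroblast markers had 5 of 9 higher and 3 lower (median 1.02, or -1.59 under poly-A control centring; adjusted p = 0.11), and endothelial markers 0 of 2 called (median 0.70, or -1.91 under that centring; adjusted p = 0.37). Epicardial markers had 1 of 5 higher and 3 lower (median -1.06, adjusted p = 0.93), and neural and ectoderm markers 0 of 4 higher and 2 lower, with 1 and 2 adjusted over the list alone (median -0.81, adjusted p = 0.93). The 1 named pluripotency marker was lower, at -3.01, and was not tested as a list.

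The 10 greatest named increases at 10 µM were smaller than the decreases. ING3, a chromatin reader, stood 2.53 ± 0.22 higher, NUP62CL 2.53 ± 0.31, MATN3, a matrix protein, 2.43 ± 0.33, and ART3 2.29 ± 0.60, the last not past the threshold with any 1 array of 0 or 10 µM left out. IFI6 (2.28), HMGN5 (2.28), PRTFDC1 (2.27), ZNF277 (2.24), PYM1 (2.19) and STAG3L4 (2.18) followed. All 10 lay between -0.44 and -0.08 under poly-A control centring. The remaining named decreases were those of TRIB1 (-6.07), PLK2, a stress-induced kinase and p53 target (-5.98), TOB1 (-5.72), EID2 (-5.62), BAMBI, a TGF-beta pseudoreceptor (-5.52), and TIPARP (-5.44). TOP2B changed by -1.57 ± 0.27 and TOP1 by -1.61 ± 0.18, while TOP2A stood at -0.67 ± 0.27 (adjusted p = 0.09). PPARGC1A changed by -3.70 ± 0.24. FAS was -0.73 ± 0.24 from its untreated level (adjusted p = 0.046), a call lost without 0 µM replicate 2 and with any 1 array of 1 or 10 µM left out. Other choices of probe set gave -0.24 and -0.19 for FAS, neither passing. MDM2 (-0.34), TNFRSF10B (-0.37), GDF15 (-0.41) and RYR2 (0.40, or -0.18 under hybridization and -2.21 under poly-A control centring) did not pass, but the MDM2 probe set with the largest spread was lower, at -1.13, after being higher at 0.1 µM, at 1.38. The p53 target list was not called against the other named genes at 10 µM against 0 µM, with 3 of 36 higher and 20 lower (median -0.64, adjusted p = 0.74). Nor was the sarcomere list, with 1 of 22 higher and 7 lower (median -0.12, adjusted p = 0.74). With fry, which does not compare a list with other genes, both passed (adjusted p = 0.00016 and 0.0019), so neither can be taken as unchanged.

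Over all probe sets, 8877 were higher and 8384 lower at 10 µM than at 0 µM, but 2303 were higher and 6168 lower by at least 2-fold. The higher share was 51.4%, against 38.8% with arrays centred on their medians, 5.48% under hybridization control centring (845 higher, 14584 lower) and 0.00367% under poly-A control centring (2 higher, 54506 lower). The last count includes probe sets near the floor, which the centring shifts like all others. The count higher was 4508 without 0 µM replicate 1, 3403 without 0 µM replicate 2 and 5279 without 10 µM replicate 2. Of the 32 lists, 4 were called upward and 3 downward.

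**Figure D3:**
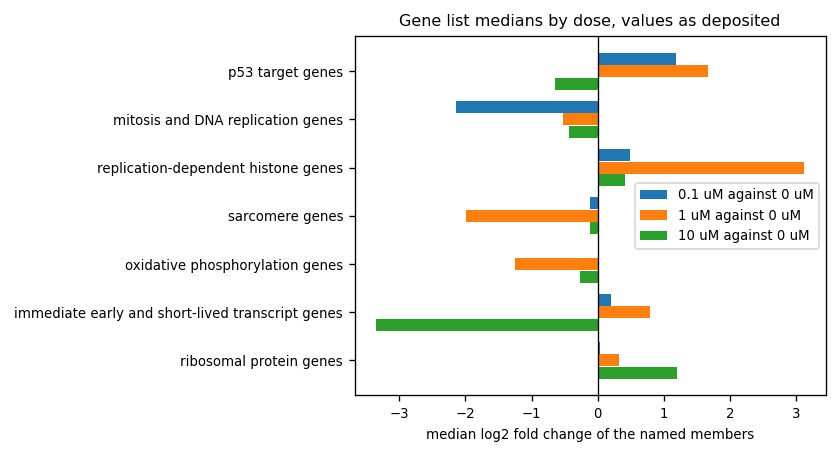
Median log2 fold change against 0 µM on the deposited scale (horizontal axis, bars start at 0) of the named members of 7 gene lists (vertical axis), with 1 bar per dose. The histone median was 3.12 at 1 µM, the sarcomere median -1.99 at 1 µM and the immediate early median -3.35 at 10 µM. Of the bars of called lists, the histone bar (0.41) and the ribosomal protein bar (1.20) at 10 µM turn to -2.20 and -1.42 under poly-A control centring, and the histone bar to -0.17 under hybridization control centring.

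Comparing neighbouring doses tested the differences between dose effects themselves. From 0.1 to 1 µM most named mitosis genes rose and most sarcomere genes fell, with the actin 3-prime to 5-prime difference going from 1.54 to 2.26. Both list calls were lost with an estimated correlation (adjusted p = 0.52 and 0.31). Of 47 mitosis and DNA replication genes, 41 were higher, 0 lower and 6 did not pass, with 43 and 0 adjusted over the list alone (median 1.57, adjusted p = 2.2e-07; adjusted p = 0.52 with an estimated correlation). That median was 0.41 under poly-A control centring, with 16 higher and 4 lower. CCNE2, cyclin E2, was higher by 5.05 ± 0.30, KIF20A by 4.18 ± 0.19, HMMR by 3.92 and ASPM by 3.79, while RRM2 stood at -0.01. For the mean of their listed probe sets, CCNE2 stood at 3.88 and ASPM at 2.63. The histone list was higher, with 27 of 29 higher, 0 lower and 2 not passing, and 29 higher adjusted over the list alone (median 2.49, or 1.33 under poly-A control centring; adjusted p = 3.8e-08; adjusted p = 0.42 with an estimated correlation). H2AC17 rose by 5.79 and H3C10 by 5.67, the latter by 5.04 without 0.1 µM replicate 1 and by 6.29 without 0.1 µM replicate 2. Ribosome biogenesis genes had 18 of 24 higher, 0 lower and 6 not passing (median 1.11, or -0.05 under poly-A control centring; adjusted p = 0.0025; adjusted p = 0.31 with an estimated correlation), with NOP56 at 2.30 and UBTF at 2.23.

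Sarcomere genes had 0 of 22 higher, 21 lower and 1 not passing between 0.1 and 1 µM (median -1.94, adjusted p = 9.9e-08; adjusted p = 0.31 with an estimated correlation), with LMOD2 at -5.10 and TCAP, telethonin, at -2.60. Of 22 calcium handling and ion channel genes, 2 were higher, 15 lower and 5 did not pass, with 3 and 15 adjusted over the list alone (median -0.93, adjusted p = 0.0041; adjusted p = 0.52 with an estimated correlation). JPH2 stood at -3.90 but CACNA1G, a T-type calcium channel, at 3.01. Load-stress genes had 1 of 12 higher, 10 lower and 1 not passing, with 1 and 11 adjusted over the list alone (median -2.13, adjusted p = 0.001; adjusted p = 0.31 with an estimated correlation), with ANKRD1 at -6.47 and ACTA1 at -3.64. Oxidative phosphorylation genes had 1 of 22 higher, 15 lower and 6 not passing, with 1 and 16 adjusted over the list alone (median -1.19, adjusted p = 0.0013; adjusted p = 0.52 with an estimated correlation), with NDUFV2 at -2.46. Cholesterol synthesis genes had 0 of 15 higher, 10 lower and 5 not passing, with 11 lower adjusted over the list alone (median -1.16, adjusted p = 0.0041; adjusted p = 0.72 with an estimated correlation), with SQLE at -2.32. Smooth muscle markers had 6 of 6 lower (median -1.51, adjusted p = 0.016; adjusted p = 0.45 with an estimated correlation), with LMOD1 at -3.69. The named genes that differed most also included NHLH2 (6.38), CNR1 (6.37), SLC4A11 (6.17), NPTX2 (5.93), ASB2 (-5.74), EPPK1, epiplakin (-5.37), and VCAM1 (-5.20). Without 1 µM replicate 1 and without 1 µM replicate 2, ANKRD1 stood at -5.26 and -7.67, ACTA1 at -2.67 and -4.61, LMOD1 at -2.88 and -4.49, and EPPK1 at -4.62 and -6.13. The medians of the 6 lists called lower lay between -3.28 and -2.09 under poly-A control centring.

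In total, 6407 probe sets were higher and 5578 lower at 1 µM than at 0.1 µM with limma. The higher share was 53.5%, against 42.6% under hybridization control centring and 3.14% under poly-A control centring (1459 higher, 45049 lower). Without 0.1 µM replicate 1, 4087 were higher, and without 0.1 µM replicate 2, 3451 were lower.

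From 1 to 10 µM, most named short-lived transcripts, p53 targets and histone genes fell and most sarcomere genes stood higher relative to other transcripts, with the actin 3-prime to 5-prime difference going from 2.26 to 1.80. These 4 list calls were lost with an estimated correlation (adjusted p = 0.5, 0.36, 0.52 and 0.31). Among all 7163 named genes, 2052 were higher and 4286 lower between these doses (median -1.21). All 40 named immediate early and short-lived transcripts were lower (median -3.83, adjusted p = 2.8e-06; adjusted p = 0.5 with an estimated correlation). They included KLF10, a growth factor-induced repressor, at -7.44 ± 0.28 (adjusted p = 3.7e-07), and ID2, an inhibitor of helix-loop-helix factors, at -6.94 ± 0.19. This list had not been called at 1 µM against 0 µM, with 22 of 40 higher and 6 lower, and 23 and 7 adjusted over the list alone (median 0.79, or -0.17 under poly-A control centring; adjusted p = 0.079). Of 36 p53 targets, 2 were higher, 31 lower and 3 did not pass, with 4 and 31 adjusted over the list alone (median -2.51, adjusted p = 0.0041; adjusted p = 0.36 with an estimated correlation). PLK2 changed by -6.56, PPM1D, a p53-induced phosphatase, by -6.13, FAS by -5.73 and TP53INP1 by -5.70. Of 29 histone genes, 0 were higher, 28 lower and 1 did not pass (median -2.49, adjusted p = 0.0013; adjusted p = 0.52 with an estimated correlation), with H2BC8 at -6.81. All 24 ribosome biogenesis genes were lower (median -2.18, adjusted p = 0.0025; adjusted p = 0.31 with an estimated correlation), with NIP7 at -3.94 and RRN3, a polymerase I initiation factor, at -3.11. The medians of these 4 lists lay between -5.48 and -3.83 under poly-A control centring.

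Apart from that of the smooth muscle markers, the medians of the lists called higher at 10 µM than at 1 µM turned negative under poly-A control centring. Under hybridization control centring they lay between 0.51 and 1.15. The list test against the other named genes reversed none of these lists under poly-A control centring, and lost the calcium list alone. A shift of all genes alike largely cancels in that test, so the kept calls have no separate support from it. Of 22 sarcomere genes, 17 were higher, 1 lower and 4 did not pass (median 1.55, or -0.10 under poly-A control centring; adjusted p = 7.3e-07; adjusted p = 0.31 with an estimated correlation). SYNPO2L stood 2.70 higher (2.00 without 1 µM replicate 1, 3.40 without 1 µM replicate 2), CMYA5 2.60 and TCAP 2.43. Of 22 oxidative phosphorylation genes, 14 were higher, 3 lower and 5 did not pass, with 15 and 3 adjusted over the list alone (median 0.92, or -0.73 under poly-A control centring; adjusted p = 7.1e-05; adjusted p = 0.5 with an estimated correlation), with ATP5MC3 3.38 higher and COX5A 2.33 higher. Of 22 calcium handling and ion channel genes, 12 were higher, 6 lower and 4 did not pass (median 0.92, or -0.74 under poly-A control centring; adjusted p = 0.027; adjusted p = 0.62 with an estimated correlation; adjusted p = 0.055 under poly-A control centring). CACNA1C stood 2.82 higher but GJC1, a connexin, stood at -4.26 and KCNJ2, an inward rectifier channel, at -3.15. Of 10 ribosomal protein genes, 8 were higher, 1 lower and 1 did not pass (median 0.95, or -0.70 under poly-A control centring; adjusted p = 0.0063; adjusted p = 0.48 with an estimated correlation), with RPS24 the lower one at -1.63.

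Of 9 fibroblast markers, 7 were higher, 1 lower and 1 did not pass between 1 and 10 µM (median 1.03, or -0.63 under poly-A control centring; adjusted p = 0.023; adjusted p = 0.52 with an estimated correlation). FBLN1 stood 1.58 higher and COL1A1, type I collagen, 1.39, or -0.08 and -0.26 under poly-A control centring. All 6 smooth muscle markers were higher (median 2.30, and 0.65 under poly-A control centring; adjusted p = 0.0013; adjusted p = 0.31 with an estimated correlation), with LMOD1 at 2.83 and MYLK at 2.73. They stood at 2.03 and 2.07 without 1 µM replicate 1 and at 3.63 and 3.39 without 1 µM replicate 2. The named genes with the greatest differences also included ABCA8, a lipid transporter (5.23), GABRP, a GABA receptor subunit (4.42), LIX1 (4.39), GTF2B, the general transcription factor TFIIB (-7.19), GCH1, which starts tetrahydrobiopterin synthesis (-6.97), and SLC30A1, a zinc exporter (-6.96). In total, 13954 probe sets were higher and 10193 lower, but 4863 were higher and 7897 lower by at least 2-fold. The higher share was 57.8%, against 22.5% under hybridization control centring, with 3752 higher, and 1.01% under poly-A control centring, with 496 higher and 48841 lower.

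Many changes seen at 1 µM were turned back at 10 µM. NHLH2 went from 2.71 at 0 µM to 9.31 at 1 µM and 2.95 at 10 µM, and CNR1 from 2.55 to 8.80 and 2.52. MYLK3, a cardiac myosin light chain kinase, went the other way, from 10.19 to 5.95 and 10.08, and ASB2 from 9.57 to 4.13 and 8.21. SLC4A11, CA2 and H2BC8 were the other named genes that rose and fell back, and LRRC49, TXLNB and ABCA8 the others that fell and came back. In total, 5184 probe sets were higher at 1 µM than at 0 µM and lower at 10 µM than at 1 µM, and 3615 went the other way. Both comparisons share the arrays of 1 µM. Independent lists of these sizes would share 1180 and 1510, and lists of these sizes with the lowest p-values from simulated groups without an effect shared 3100 and 3550. The simulated lists are ranked by noise in the shared arrays, so they set no expectation for lists that hold changes between doses. Under poly-A control centring the counts were 1766 and 494, and part of any excess may come from the shared arrays.

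Calls were also compared between doses, each against the same untreated arrays. Those higher at both 0.1 and 1 µM numbered 48, and those lower at both 62, where independent lists would share 6.82 and 14.9. In opposite directions, 5 were higher at 0.1 µM and lower at 1 µM (6.4) and 20 lower then higher (15.8). The 5 were probe sets of KRT19, TMEM40 (2 of them), DNAJA4 and PROSER2, named because they were few and after their values were seen. At 0.1 and 10 µM, 6 were higher at both (9.59), 57 lower at both (21), 24 higher then lower (9.06) and 20 lower then higher (22.3). At 1 and 10 µM, 881 were higher at both (independent lists 1030) and 2305 lower at both (910), while 2061 were higher at 1 µM and lower at 10 µM (969) and 862 lower at 1 µM and higher at 10 µM (963). Simulated groups without an effect shared 0 calls in each of these, but they had 0.12 calls per comparison, so that this value sets no expectation for lists of the observed sizes. Lists of those sizes with the lowest p-values from the simulated groups shared 43.1 higher, 94.2 lower, 0.85 higher then lower and 1.7 lower then higher at 0.1 and 1 µM, 45.8, 102, 0.95 and 3.2 at 0.1 and 10 µM, and 2830 higher, 2610 lower, 178 higher then lower and 176 lower then higher at 1 and 10 µM. The observed overlaps in 1 direction were below these values, except for higher calls at 0.1 and 1 µM, and those in opposite directions were above them. These simulated lists are ranked by noise alone, which the shared controls correlate. They set no expectation for lists that hold changes between doses, and no conclusion is drawn from them. The covariance of log2 fold changes was 0.0412 between 0.1 and 1 µM and 0.032 between 1 and 10 µM. Simulated values from the shared controls alone were 0.0244 and 0.0243. The correlations were r = 0.196 and 0.046, beside a simulated 0.499 that the shared controls fix without an effect. That simulated r sets no expectation for doses with changes. With 2 control arrays these could not be split, so part of an excess may come from the shared controls. The overlap at 0.1 and 1 µM fell to 8 higher and 29 lower without 0 µM replicate 1, 2 and 1 without 0 µM replicate 2, 1 and 1 without 0.1 µM replicate 1, 9 and 31 without 0.1 µM replicate 2, and 30 and 35 with each array of 10 µM left out in turn. With 1 array of 0 or 0.1 µM left out, the other overlaps of 0.1 µM fell to 0 higher then lower and 0 to 9 lower then higher at 1 µM, and to 0 to 3 higher, 1 to 28 lower, 1 to 2 higher then lower and 0 to 11 lower then higher at 10 µM. With each array of 10 µM left out in turn, 2 were higher then lower and 13 lower then higher at 1 µM, while at 10 µM 13 and 12 were higher then lower and 6 and 9 lower then higher, with 33 lower at both without 10 µM replicate 2. With each array of 1 µM left out, 9 and 11 were higher at 0.1 µM and lower at 1 µM, and 13 higher at 0.1 and 10 µM. With 1 array left out, the overlaps at 1 and 10 µM were lowest without 0 µM replicate 1 (350 higher at both, 1518 lower at both, 1116 higher then lower, 291 lower then higher) and without 0 µM replicate 2 (374, 1345, 1116 and 262). Control centring moved them further, to 0 higher at both, 40517 lower at both and 0 lower then higher with the poly-A controls, and to 127, 3971 and 169 with the hybridization controls. With the poly-A controls, 24 were higher at 0.1 µM and lower at 1 µM, 4 lower then higher, and at 0.1 and 10 µM 0 were higher, 101 lower, 100 higher then lower and 0 lower then higher.

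The authors' deposited lists held 120 probe sets higher and 197 lower at 0.1 µM, of which 57 and 128 were called the same way here. At 1 µM, 3199 of 3206 listed as higher and 2675 of 2680 listed as lower were called the same way, and at 10 µM 1784 of 1803 and 5085 of 5104. None was called in the opposite direction at any dose. In the other direction, at the authors' limit of 2-fold this fit called 4172 higher and 3630 lower at 1 µM, of which 981 and 964 were not listed, and 2303 and 6168 at 10 µM, of which 546 and 1102 were not. At 0.1 µM, 0 of 57 and 8 of 136 were not listed. The listed probe sets not called at 0.1 µM all had the listed sign and an unadjusted p under 0.05.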

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

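All tests in this part were chosen after the results they bear on were seen. Control probe sets outside the comparisons differed between doses and the untreated arrays. The poly-A controls, RNA usually added to the sample RNA before labelling, were higher by 0.96 at 1 µM and by 2.61 at 10 µM on the log2 scale (6.12-fold at 10 µM), in both replicate numbers (3.02 and 2.21 at 10 µM). The hybridization controls were higher by 0.18 at 1 µM, where the replicate numbers gave 0.48 and -0.12, and by 0.59 at 10 µM. The trpn probe sets, which have no human target, were higher by 0.30 at 10 µM (0.22 and 0.38).

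For the poly-A rise at 10 µM, normalization that lifted all control probe sets alike is argued against. The bioB probe sets, the dimmest hybridization controls, rose by 1.04 (1.26 and 0.81 by replicate number), less than the poly-A rise in both. The comparison is not brightness-matched, since bioB stood at 7.86 and the poly-A controls at 5.23 at 0 µM, and probe sets of the brightness of the latter had a median change of 0.15 to 0.32. The poly-A rise exceeded the hybridization rise by 2.03, which less sample RNA set against a fixed amount of control RNA could give. Whether the control RNA was added by RNA mass or by cell number or volume is not given in the sources used here, so lower RNA content per cell, cell loss and a handling difference between doses cannot be told apart.

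Of the 8877 probe sets higher at 10 µM, 6574 were higher by less than 2-fold. These were not concentrated among dim probe sets, since 59.3% of them lay in the 6 dimmest deciles, which hold 60% of all probe sets. Over the 6 dimmest deciles of probe sets the median rise was 0.24. The trpn probe sets rose by 0.30, a similar amount, which a lifted floor on the 10 µM arrays, for example from normalization, could give. The comparison is not brightness-matched, since the trpn probe sets stood at 2.63 and 2.73 at 0 µM. The deciles nearest to them, with mean signals of 2.57 and 2.97, had smaller median rises of 0.14 and 0.20. A lifted floor would not account for the small increases of brighter probe sets, and no biological explanation was tested.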

How the results depend on the processing

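Tests with centring on control probe sets and with 1 value per named gene were chosen after the results were seen, and the other settings beforehand. Quantile normalization, leaving out the lowest 30% of probe sets by mean signal, the robust prior with a trend and the replicate block moved none of the 24 counts they were run on by over 1.5 times, and, apart from the prior, which was not run on lists, lost none of the 44 list calls. Of 330 named values, quantile normalization gained 4 calls and lost 1 (TNFRSF10A at 0.1 µM), the dim filter gained 2, the prior 5, and the block gained 4 and lost 1 (FANCI at 0.1 µM). The mean of a gene's listed probe sets gained 23 and lost 2, and the one of largest spread gained 19 and lost 2, both fitted and adjusted over the named genes alone. Sign changes of a named value that passed before or after arose under poly-A control centring alone, 51 of 330 values. Values that passed in neither also changed sign, 14 under poly-A and 15 under hybridization control centring, and at most 5 in each other setting. Centring on the ribosomal protein list was not run, because 10 of its 60 members had a named probe set, all selected as changed, and a pseudocount was not needed for values already on a log scale. The limit of detection of these arrays was not measured, and the dimmest decile of probe sets, with a mean signal of 2.57, had 130 higher and 6 lower calls at 10 µM. The cause of the differences that follow was not tested, unless it lies in a stricter threshold, fewer arrays or fewer probe sets.

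By the correlation of their differences, the replicate numbers did not pair the samples of all doses, since every pair among 0, 0.1 and 1 µM was over 0.1 and no pair with 10 µM was (0.56 for 0 and 0.1 µM, 0.31 for 0 and 1 µM, -0.015 for 0 and 10 µM, 0.27 for 0.1 and 1 µM, -0.099 for 0.1 and 10 µM, 0.09 for 1 and 10 µM). The third principal component and the control probe sets differed by replicate number at every dose, so that a shared batch stays open. With the replicate number as a block, 72 were higher and 149 lower at 0.1 µM, 6840 and 6516 at 1 µM, 10109 and 9020 at 10 µM, 6955 and 6191 for 1 against 0.1 µM, and 15133 and 10732 for 10 against 1 µM.

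With poly-A control centring, 101 were higher at 0.1 µM, 1766 higher and 40577 lower at 1 µM, 2 and 54506 at 10 µM, 1459 and 45049 for 1 against 0.1 µM, 496 and 48841 for 10 against 1 µM. Those that turned back were 1766 and 494, and overlaps of 1 and 10 µM were 0 higher, 40517 lower and 0 lower then higher, those of 0.1 and 1 µM 24 higher then lower and 4 lower then higher, and those of 0.1 and 10 µM 0 higher, 101 lower, 100 higher then lower and 0 lower then higher. With hybridization control centring, 119 were higher and 246 lower at 0.1 µM, 845 and 14584 at 10 µM, and 3752 higher for 10 against 1 µM, with overlaps of 73 higher, 108 lower, 17 higher then lower and 32 lower then higher at 0.1 and 1 µM, 167 lower and 70 higher then lower at 0.1 and 10 µM, and 127 higher, 3971 lower and 169 lower then higher at 1 and 10 µM. Median centring gave 5702 higher at 10 µM, and the 4 compared arrays alone 82 lower at 0.1 µM and overlaps of 36 lower, 3 higher then lower and 10 lower then higher at 0.1 and 1 µM, and of 7 lower then higher at 0.1 and 10 µM.

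At an adjusted p under 0.01, 12 were higher and 34 lower at 0.1 µM, 3802 lower at 1 µM, 3183 higher at 10 µM, 3521 lower for 1 against 0.1 µM, 7252 higher for 10 against 1 µM, and 2181 lower at 1 µM turned back. Overlaps were then 9 higher, 11 lower, 0 higher then lower and 2 lower then higher at 0.1 and 1 µM, 1, 12, 2 and 2 at 0.1 and 10 µM, and 300 higher, 1272 lower, 1089 higher then lower and 276 lower then higher at 1 and 10 µM. With a change of at least 2-fold, 4172 were higher and 3630 lower at 1 µM, 2303 higher at 10 µM, 3289 lower for 1 against 0.1 µM, 4863 higher for 10 against 1 µM, 1901 lower at 1 µM turned back, overlaps at 0.1 and 10 µM were 3 higher and 13 lower then higher, and overlaps at 1 and 10 µM were 232 higher, 1215 lower, 1024 higher then lower and 206 lower then higher. With 1 value per named gene, 109 were higher and 209 lower at 0.1 µM, 2749 and 2422 at 1 µM, 1514 and 4180 at 10 µM, 2855 and 2306 for 1 against 0.1 µM, 2140 and 4370 for 10 against 1 µM, and 2489 and 1388 turned back. By sign alone, and at an unadjusted p under 0.05, 120 of the authors' higher and 197 of their lower probe sets at 0.1 µM went the same way.

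Leaving out 1 array gave 2 to 82 higher and 2 to 153 lower at 0.1 µM, 4223 to 6363 higher and 3947 to 5957 lower at 1 µM, 3403 to 9303 higher and 6342 to 8766 lower at 10 µM, 4087 to 6493 and 3451 to 5662 for 1 against 0.1 µM, 9577 to 12549 and 8880 to 9870 for 10 against 1 µM, and 3718 to 4976 and 2461 to 3321 turned back. Overlaps ranged from 1 to 54 higher, 1 to 59 lower, 0 to 11 higher then lower and 0 to 21 lower then higher at 0.1 and 1 µM, from 0 to 13, 1 to 69, 1 to 34 and 0 to 22 at 0.1 and 10 µM, and from 350 to 960 higher, 1345 to 2146 lower, 1116 to 2004 higher then lower and 262 to 992 lower then higher at 1 and 10 µM. The lowest counts at 0.1 µM came without 0.1 µM replicate 1 (2 higher, 2 lower) and without 0 µM replicate 2 (3 and 3). The smooth muscle call at 10 µM ranged from 0.033 to 0.057.

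With an estimated correlation, 43 of 44 list calls were lost, and camera then gave adjusted p values of 0.31, 0.36, 0.38, 0.39, 0.42, 0.45, 0.47, 0.48, 0.5, 0.52, 0.62, 0.72 and 0.74. With 4 residual degrees of freedom this variant has little power, so these losses cannot tell whether a list moved. The preset correlation treats the genes of a list as nearly independent, so the p-values that it gave may be far too small. fry lost 4, the immediate early (0.16) and interferon (0.055) lists at 0.1 µM, the histone list at 10 µM (0.1) and the calcium list for 10 against 1 µM (0.3). It also passed lists that camera did not call, among them oxidative stress at 1 µM (0.00032) and heat shock at 10 µM (9.6e-05). Since the named genes were selected as changed, passing fry does not set a list apart from them. Poly-A control centring lost 5, ribosome biogenesis at 1 µM (0.054), ZNF (0.12), smooth muscle (0.067) and endoderm (0.055) at 10 µM, and calcium for 10 against 1 µM (0.055). The list calls kept under that centring are no separate support, since a shift of all genes alike largely cancels in camera.

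Under poly-A control centring, log2 fold changes at 10 µM against 0 µM became -0.08 for ING3 and NUP62CL, -0.19 for MATN3, -0.33 for ART3 and IFI6, -0.34 for HMGN5, -0.35 for PRTFDC1, -0.37 for ZNF277, -0.43 for PYM1, -0.44 for STAG3L4, -2.50 for MYH6, -2.21 for RYR2, -2.38 for NHLH2, -2.26 for SLC4A11, -2.54 for CA2, -1.38 for ABCA8, -2.51 for NR2F1, -1.04 for H2BC4, -1.22 for H1-2, -1.31 for H4C8, -2.20 for H2BC12, -2.23 for H2AC6, -0.61 for RPS23, -0.67 for RPL31, -0.73 for RPL23, -1.33 for RPL10, -1.04 for TAGLN, -1.52 for MYLK, -1.71 for CALD1, -2.52 for ACTG2, -1.99 for MYH11, -1.33 for EPCAM, -1.41 for AFP and -1.49 for APOA1. At 1 µM against 0 µM, they became -0.25 for CDKN1A and -0.89 for DKC1. For 10 against 1 µM, they became -0.86 for RPS27L, -1.13 for CMBL, -1.43 for TTN, -1.18 for TNNI3, -1.46 for CACNB2, -1.27 for KCNA5, -1.47 for NDUFB10, -1.20 for NDUFA10, -0.17 for RPL10, -0.23 for RPL13, -1.35 for RPL37, -0.08 for FBLN1, -0.26 for COL1A1, -0.42 for DDR2 and -0.51 for POSTN.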

Other observations

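The tests in this part were all chosen after the results they bear on were seen, and none was planned. Families of genes that share a symbol root were compared with the other named genes by exact Fisher tests, 486 tests over 81 families of at least 10 named members, with Benjamini-Hochberg adjustment. These tests treat genes measured on the same arrays as independent, so their p-values may be far too small. The fixed ZNF list at 10 µM was not called by camera with an estimated correlation (adjusted p = 0.5). The KIF, MCM, TNFRSF and H families share members with lists called above, so they add no separate support. At 10 µM, 177 of 207 named ZNF genes were lower than at 0 µM (median -1.67, adjusted p = 3.8e-17), against 55.5% of other named genes. All 11 of 11 UTP genes, of the small-subunit processome, were lower, against 56.3% of other named genes, without passing (adjusted p = 0.08). At 0.1 µM, 8 of 16 KIF genes, which encode kinesins, were lower (against 1.3% of other named genes, adjusted p = 3.4e-09), as were 4 of 10 MCM genes, which encode parts of the replicative helicase family (against 1.36%, adjusted p = 0.00059), and 3 of 10 TNFRSF genes were higher (against 0.531%, adjusted p = 0.0012). At 1 µM, 76 of 120 LOC genes, a root for loci without a given name, were higher (against 34.7% of other named genes, median 1.33, adjusted p = 4e-08), as were 31 of 36 H genes, which include histones (against 35%, median 2.94, adjusted p = 4.6e-08), while 21 of 30 MRPL genes, of the large mitochondrial ribosome subunit, were lower (against 30.7%, median -1.03, adjusted p = 0.00081). At 10 µM, 14 of 17 COL genes, which encode collagens, were higher with a median of 1.15, or -1.46 under poly-A control centring (against 19.3% of other named genes, adjusted p = 3.8e-06), and 9 of 14 CD genes were higher with a median of 1.05, or -1.57 under that centring (against 19.3%, adjusted p = 0.016).

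The fall of immediate early and short-lived transcripts between 1 and 10 µM was weighed against technical explanations. RNA degradation that raises the difference between 3-prime and 5-prime control probe sets by 0.5 or more is argued against, since that difference changed by 0.05 ± 0.09 in GAPDH (SE, n = 2 per dose) and by -0.46 ± 0.23 in actin, while a smaller degree stays open. For actin the 1 µM arrays were those that stood apart (1.82 at 0 µM, 1.54 at 0.1 µM, 2.26 at 1 µM and 1.80 at 10 µM), so that the argument rests on GAPDH alone. From 0 to 10 µM the difference changed by -0.05 ± 0.08 in GAPDH. In actin it changed by -0.01 ± 0.24, too imprecise with 2 arrays per dose to argue against a rise of 0.5. A candidate explanation is lower transcription at 10 µM, which would leave long-lived transcripts relatively high. The oxidative phosphorylation list, taken as mostly long-lived, lay at percentile 97.2 of 10000 random lists of named genes matched on mean signal against 1 µM but at 82.6 against 0 µM, so that explanation stays open, and transcript lifetimes were not measured here.

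Between replicate numbers the spread at 1 µM was wider than in untreated cells, with 3.05% of probe sets over 2-fold apart at 1 µM, 1.56% at 10 µM, 0.859% at 0 µM and 0.555% at 0.1 µM. The third principal component, with 4.39% of the variance, had the opposite sign in the 2 replicate numbers at every dose, with scores of 42.7 and -40.5 at 1 µM and of 5.25 and -5.71 at 10 µM.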
